A study of Mus musculus with 24 samples.

How the data were processed

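Regulatory T cells (Tregs) from the visceral adipose tissue (VAT) of 24 male mice were measured on a custom NanoString nCounter panel of 96 genes. Per the labels' protocols, tissue from each animal was digested separately, so each sample is a separate mouse. Cells were sorted as CD45+ CD4+ Foxp3(YFP)+, lysed and counted on an nCounter SPRINT Profiler. Control mice carried the Foxp3-YFP-Cre allele alone, and knockout mice carried it with a floxed insulin receptor gene, which deletes Insr in Tregs. The labels also state that this Cre line can recombine outside Tregs. The groups were 4 control and 5 knockout mice on a high-fat, high-sucrose diet (HFD), 3 control and 3 knockout mice on normal chow (NCD), and 3 control and 6 knockout mice aged to 52 weeks on chow. HFD and NCD mice were on their diet for 13 weeks from 3 weeks of age, that is to 16 weeks.

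The deposited values are nCounter signal that the authors scaled per sample to a panel total of 100000; they are linear and not logged. The unit was read from the values, since background correction, scaling by positive controls and the software are not given in the sources used here. In 2302 of the 2304 values the signal was a whole multiple of a step specific to its sample, within 0.02 of a count, so the counts behind each sample could be read off. The 2 exceptions were CD25 in aged knockout replicate 1 and Il1rl1 in aged knockout replicate 5. Values at 0 numbered 5. The 96 values summed to 100000 in 12 of the 14 knockout samples and to more in the other 2 and in all 10 control samples. Panel names were matched to mouse gene symbols: 89 matched a symbol, 3 a synonym, 1 (TGFb) several symbols and 3 (LeptinR, Perforin, Rorgt) none. These 4 keep the panel's name and joined no gene list.

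The recovered total per sample ran from 11446 counts (NCD knockout replicate 3) to 224793 counts (HFD knockout replicate 5), with a median of 49098, a 19.6-fold range. The 3 NCD knockout samples had the lowest median depth of the 6 groups. Genes with few counts have a counting error that adds to the spread between mice. Intervals for pooled counts were 95% exact binomial intervals and cover counting error only. They treat each count as an independent draw, which was not tested, and are too narrow where counts are not independent.

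Values were transformed as log2(signal + 1). limma 3.58.1 in R 4.3.3 fitted a mean for each of the 6 groups to all 24 samples (lmFit, contrasts.fit, eBayes). Two-sided p values were adjusted by Benjamini-Hochberg over the 96 genes of each contrast, with a threshold of 0.05. No gene was filtered out and no sample was left out. The 10 contrasts, fixed before the data were examined, were knockout against control in each setting and their mean with equal weights, HFD against NCD and aged against young in each genotype, and the interactions of genotype with diet and with age. The difference between the genotype effects in aged and HFD mice was added after the data were seen.

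Named genes followed a rule fixed before the data were examined. In each contrast of 2 groups, and for the mean genotype effect, all passing genes were taken, up to the 25 with the smallest p, or the 10 with the smallest p where fewer than 10 passed. For genotype contrasts Insr, Foxp3, Il1rl1, Pparg, Gata3, Klrg1, Il10 and Areg were always taken. Nt5e, Entpd1 and Mki67, also in the rule, are not on the panel. Interactions took the 5 smallest p where none passed.

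Of 23 gene lists fixed from textbook knowledge, 11 had at least 3 members on the panel and were tested with limma's fry. They were visceral adipose Treg genes (14 measured), core Treg identity (7), Treg suppressive effectors (6), naive and lymphoid-type T cell genes (3), Th2 genes (4), chemokine receptors and adhesion (9), insulin and PI3K-mTOR signalling (3), fatty acid and lipid metabolism (3), checkpoint and activation receptors (6), cytokine receptors and STAT signalling (3) and reference genes (4). Fry tests whether a list moves on balance in 1 direction and does not compare the list with other genes. Camera, which does, was run with a preset correlation and with an estimated correlation. List p values were adjusted over the 11 lists of a contrast. Results for the naive and lymphoid-type list, and for 2 genes that the naming rule takes, are not reported here, although counts of genes and lists include them.

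Alternatives fixed at the same time were pseudocounts of 0.1 and 10, leaving out the 24 genes with the lowest mean, centring on the sample median or on 4 reference genes (Gusb, Hprt, Rpl19, Sdha), fitting only the groups of a contrast, array weights, a variance trend with a robust prior, a replicate block, and leaving out each sample in turn. Alternatives chosen after the data were seen were rescaling each sample to a single total, voom on the recovered counts, log2 total count as a covariate, leaving out genes under 20 counts in most samples, setting the 2 non-whole values to missing, and leaving out samples in turn for the list tests. The other splits of the samples were enumerated, or 100 were drawn. In a test on simulated data, with normal noise around each gene's measured mean and 20 genes shifted in each contrast, the fit recovered most shifts of 4 log2 units and few of 1. Python 3.11.15 with scipy 1.17.1 read the files, and matplotlib 3.10.9 drew the plots.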

Results

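The series asked how deletion of the insulin receptor in Tregs changes the expression of 96 genes in VAT Tregs of mice that are hyperinsulinaemic on HFD or at 52 weeks of age, with young chow-fed mice beside them. Recovered totals per sample were 24005 to 152648 counts in HFD controls (n = 4), 34986 to 224793 in HFD knockouts (n = 5) and 17371 to 141932 in NCD controls (n = 3). They were 11446 to 23790 in NCD knockouts (n = 3), 27591 to 94023 in aged controls (n = 3) and 21487 to 135141 in aged knockouts (n = 6). Pearson's r across genes on log2 values was 0.81 to 0.98 between samples of a group; genes are not independent replicates.

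InsR, the deleted gene, was lower in every knockout mouse than in every control mouse of the same setting. Its signal was 92.0 ± 31.7 in HFD controls (SD, n = 4) and 5.43 ± 3.04 in HFD knockouts (n = 5), 106.9 ± 49.7 in NCD controls (n = 3) and 10.5 ± 6.66 in NCD knockouts (n = 3), and 388 ± 112 in aged controls (n = 3) and 7.64 ± 5.85 in aged knockouts (n = 6). On pooled counts, InsR had 21 counts in HFD knockouts and 272 in HFD controls, a control to knockout ratio per panel count of 18.9 (95% exact interval 12.1 to 31.1). The counts were 5 and 175 on NCD (ratio 10.03, 4.22 to 31.3) and 18 and 760 in aged mice (ratio 81.0, 50.9 to 137). Each knockout mouse had 1 to 6 InsR counts, as few as the weakest probes of the panel give (Il5, 1 to 6 in the same mice). The intervals cover counting error for independent counts only, and any background in these counts would make the ratios too small. The position of the probe relative to the deleted exon is not given in the sources used here.

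**Figure D1:**
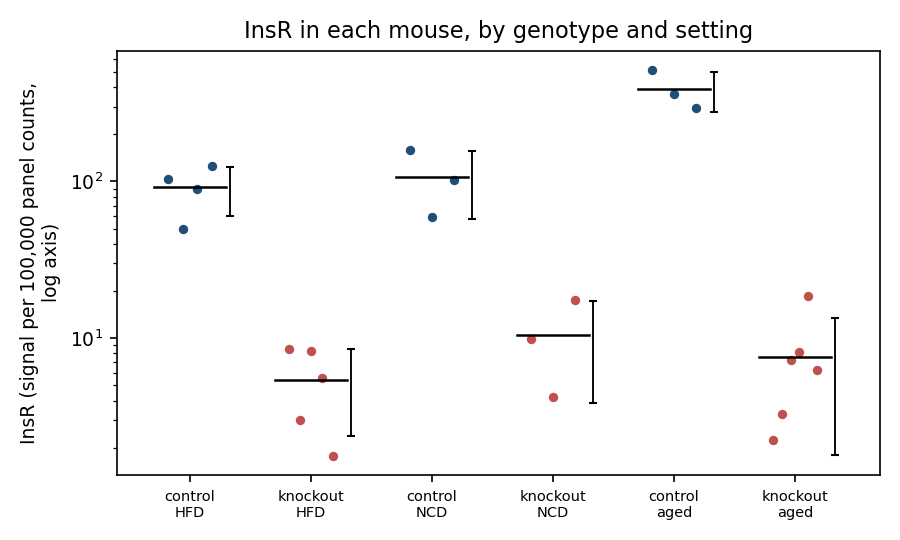
InsR signal (per 100000 panel counts, log axis) in each mouse, with control mice in blue and knockout mice in red for HFD, NCD and aged groups. Points are mice, horizontal lines are group means and vertical bars are SD; the 14 knockout mice lie below the 10 control mice.

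In HFD mice, 2 of the 96 genes passed in knockout against control Tregs, both lower: InsR, with log2 fold change -3.93 (SE 0.51, adjusted p = 9.49e-06 by limma with Benjamini-Hochberg), and Rorgt. Rorgt, the panel's name for the transcription factor of Th17 cells, fell from 946 ± 779 (SD, n = 4) in controls to 92.7 ± 79.5 (n = 5) in knockouts. Its log2 fold change was -3.39 (SE 0.80, adjusted p = 0.015), and all 5 knockout mice lay below all 4 controls. HFD knockout replicates 1, 3 and 5 had 32, 33 and 33 Rorgt counts at totals of 34986, 60601 and 224793. Counts that do not follow depth may be a floor, so the size of the fall and the knockout SD are uncertain. Counts of 31 to 35 also occurred in NCD knockout replicate 1 and aged knockout replicates 1, 2, 3 and 6. Other Rorgt comparisons with knockouts share this limit. IL-10, a suppressive cytokine, had a signal of 107 ± 30.9 in knockouts and 42.0 ± 16.1 in controls, with log2 fold change 1.36 (SE 0.40), and did not pass (adjusted p = 0.076). Foxp3, the Treg lineage factor, had a log2 fold change of 0.03 (SE 0.47), Il1rl1, the IL-33 receptor, 0.29 (SE 0.47), Pparg 0.42 (SE 0.43), Gata3 0.29 (SE 0.53), Klrg1 -0.18 (SE 0.81) and Areg -0.09 (SE 0.44). None of these 6 passed, and Foxp3, Klrg1 and Areg changed sign under some scalings or without single mice. Others among the 10 smallest p that did not pass were Il5 (-1.77), Klf4 (1.498), TGFb (0.79), Perforin (-1.18) and Pcsk1 (1.18), with adjusted p from 0.21 to 0.40.

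Of the gene lists in HFD mice, insulin and PI3K-mTOR signalling moved down by fry (adjusted p = 0.0014) through InsR, with IGF1R at 0.20 and Irs2 at 0.38 log2. Its median was 0.20 and its mean -1.12, and the list did not pass by camera (adjusted p = 0.48 with an estimated correlation). No member of the visceral adipose Treg genes (0 of 14), core Treg identity (0 of 7) or suppressive effectors (0 of 6) passed over all genes; adjusted over the list alone, 1, 0 and 1 did, by limma in each case. Across the whole panel 11 genes had an unadjusted p under 0.05, and voom on recovered counts called 4 genes and array weights 5. Rorgt did not pass without control replicate 1 (adjusted p = 0.080), control replicate 2 (0.10) or knockout replicate 5 (0.067), nor with the HFD mice fitted alone or with a replicate block (0.076 in each).

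Scaling moved the median of all genes in several contrasts. Centring on 4 reference genes shifted the HFD genotype median by 0.31 log2 and the NCD genotype median by -0.39, and then called 3 genes in each, 1 of them higher; it shifted the aged genotype median by -0.17. Centring on the sample median shifted the NCD genotype median by 0.23, the aged genotype median by 0.87 and the median of the mean genotype effect by 0.38. The changes below are relative to the panel total that the authors used, unless a centring is named.

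In NCD mice, 5 genes passed in knockout against control Tregs, 3 higher and 2 lower. InsR fell by 3.30 on the log2 scale (SE 0.62, adjusted p = 0.0022), and Ccr2, a chemokine receptor, fell by 2.21 (SE 0.61, adjusted p = 0.033), from 744 ± 513 (SD, n = 3) to 146 ± 63.6 (n = 3). Lmna, which encodes lamin A/C, rose from 110 ± 21.9 to 531 ± 58.8, a log2 fold change of 2.28 (SE 0.48, adjusted p = 0.005). Ccr7, the receptor that guides T cells to lymph nodes, rose from 244 ± 249 to 1350 ± 729 (log2 fold change 2.81, SE 0.69, adjusted p = 0.015). Irs2, an adaptor of the insulin receptor, rose from 311 ± 177 to 911 ± 365 (log2 fold change 1.62, SE 0.46, adjusted p = 0.038). Each of the 5 had all 3 knockout mice on the same side of all 3 controls, which chance gives in 10% of genes not picked by p.

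Klrg1, a marker of differentiated effector cells, had a signal of 2397 ± 805 in NCD controls and 270 ± 94.3 in NCD knockouts and did not pass (log2 fold change -3.15, SE 0.99, adjusted p = 0.066). Il1rl1 (-1.17, SE 0.58), Areg (-0.59, SE 0.53), Pparg (-0.49, SE 0.52), Gata3 (-0.40, SE 0.65), IL-10 (-0.09, SE 0.48) and Foxp3 (0.07, SE 0.58) did not pass; IL-10 and Foxp3 changed sign under some alternatives. Ebi3 (1.26), Ccr3 (2.15), Cxcl2 (-1.08) and Myadm (-1.12) had the next smallest p, with adjusted p from 0.083 to 0.34. No list passed by fry or camera in NCD mice, where 12 genes had an unadjusted p under 0.05. Among the chemokine receptors and adhesion genes 1 of 9 rose, 1 fell and 7 did not pass, and 3 passed adjusted over the list alone. Among the visceral adipose Treg genes 1 of 14 fell, and 2 passed adjusted over the list alone. The insulin list had 1 gene that rose and 1 that fell, a median of 0.17 and a mean of -0.50. InsR and Lmna passed without any single mouse. The calls of Ccr7, Ccr2 and Irs2 were each lost without knockout replicate 1 (adjusted p = 0.11, 0.14 and 0.11), knockout replicate 2 (0.054, 0.0999 and 0.18) or control replicate 2 (0.16, 0.074 and 0.17). Ccr7 also failed without control replicate 1 (0.058), and Ccr2 and Irs2 failed without control replicate 3 (0.22 and 0.23). The count was 3 without control replicate 3 and 2 without control replicate 2, knockout replicate 1 or knockout replicate 2. After centring on reference genes Lmna (adjusted p = 0.075) and Irs2 (0.27) failed. Fitting the NCD mice alone ended the calls of Ccr7 (0.13), Ccr2 (0.0999) and Irs2 (0.18), a replicate block those of Ccr2 (0.069) and Irs2 (0.088), and the depth covariate that of Irs2 (0.080).

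In aged mice, 23 genes passed in knockout against control Tregs, 20 lower and 3 higher, with a median of all genes of -0.60 log2. Foxp3 fell from 1784 ± 419 (SD, n = 3) in controls to 687 ± 463 (n = 6) in knockouts, a log2 fold change of -1.69 (SE 0.50, adjusted p = 0.021). Il1rl1 fell from 3262 ± 1651 to 559 ± 359 (-2.62, SE 0.50, adjusted p = 0.0013). IL-10 fell from 349 ± 77.6 to 86.9 ± 34.9 (-2.07, SE 0.42, adjusted p = 0.0019). CD25, the alpha chain of the IL-2 receptor, fell from 2627 ± 1071 to 731 ± 851 (-2.35, SE 0.54, adjusted p = 0.0042). Igfbp7, a secreted protein made by stromal and endothelial cells, rose from 1111 ± 976 to 5452 ± 2606 (2.69, SE 0.88, adjusted p = 0.030), as did Cd9 (1.92, SE 0.55, adjusted p = 0.021) and Trib1 (1.16, SE 0.36, adjusted p = 0.026). For all 23 genes the 6 knockout mice lay beyond the control mean, and for 13 of them the 6 lay beyond every control mouse, which chance gives in 2.38% of genes not picked by p.

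Among the visceral adipose Treg genes of aged mice, 5 of 14 fell (Il1rl1, Klrg1, Areg, Irf4 and IL-10) and 9 did not pass, with 6 passing adjusted over the list alone. Klrg1 had a log2 fold change of -2.56 (SE 0.86) and Areg, a tissue repair factor, -1.84 (SE 0.46), whereas Pparg (-0.54, SE 0.45) and Gata3 (-0.95, SE 0.56) did not pass. The list moved down by fry (adjusted p = 0.00056), and camera gave adjusted p = 0.42 with an estimated correlation. Of core Treg identity, 3 of 7 fell (Foxp3, CD25 and Helios) and 5 passed adjusted over the list alone (fry adjusted p = 0.0015, camera adjusted p = 0.42 with an estimated correlation). Of the suppressive effectors, 4 of 6 fell (IL-10, Areg, Pdcd1 and GzmB), and 4 passed adjusted over the list alone (fry adjusted p = 3.58e-05, camera adjusted p = 0.33 with an estimated correlation). The checkpoint receptors had 3 of 6 that fell (Pdcd1, Cd69 and Klrg1), and 5 passed adjusted over the list alone (fry adjusted p = 0.00056, camera adjusted p = 0.42 with an estimated correlation). All 3 cytokine receptors fell (CD25, Il1rl1 and Il10ra) and passed over the list alone (fry adjusted p = 1.52e-05). This list also passed by camera with a preset correlation (adjusted p = 0.044) but not when it was estimated (adjusted p = 0.32 with an estimated correlation). The Th2 list (1 of 4 fell, Il1rl1, fry adjusted p = 0.0017) and the insulin list (1 of 3 fell, InsR, fry adjusted p = 5.14e-07) each had adjusted p = 0.42 with an estimated correlation. The fatty acid and lipid list had 1 of 3 that fell, Dgat1, and did not pass (fry adjusted p = 0.32). The reference genes had 0 of 4 passing by limma, 0 adjusted over the list alone and a median of 0.12 log2.

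Among lists that did not pass, median and mean differed in sign for the Th2 list in HFD mice (0.29 and -0.11), for the chemokine receptor list in NCD mice (-0.05 and 0.15), in HFD against NCD knockouts (0.21 and -0.53) and in aged against young controls (0.25 and -0.09), and for the checkpoint list in NCD mice (0.04 and -0.40) and in HFD against NCD controls (0.16 and -0.63). The effectors in NCD mice (median -0.07) and the checkpoint list in HFD against NCD knockouts (median -0.11) had negative medians and means and an upward sign by fry.

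Of the remaining genes that fell in aged knockouts, Il10ra had log2 fold change -1.99, Helios -1.82, Pdcd1 -1.91, Nfkbid -2.34, S100a6 -2.35, Mmp9 -2.55, GzmB -2.21, Tbet -2.09, Satb1 -2.00, Pcsk1 -1.94, Dgat1 -1.70, Irf4 -1.46 and Cd69 -1.31. Mmp9 had only 10 to 20 counts in each aged knockout mouse. Tbet was the single measured member of the Th1 list. Lyz2, a macrophage gene, differed by -0.20 (SE 1.11) and the T cell receptor gene Tcra by -2.68 (SE 1.05), neither passing. InsR, Il1rl1, IL-10, Il10ra, Helios, CD25 and Pdcd1 passed without any single mouse. The count was 9 without control replicate 2, 11 without control replicate 3, 13 without control replicate 1 and 10 without knockout replicate 2, and Igfbp7 had adjusted p = 0.24 without control replicate 2 and Foxp3 0.080 without control replicate 3. After centring on the sample median 16 genes passed, 14 higher and 2 lower (InsR and Il1rl1). After centring on 4 reference genes 23 passed, 20 lower and 3 higher, 22 of them among the 23 above. Fitting the aged mice alone called 5.

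**Figure D2:**
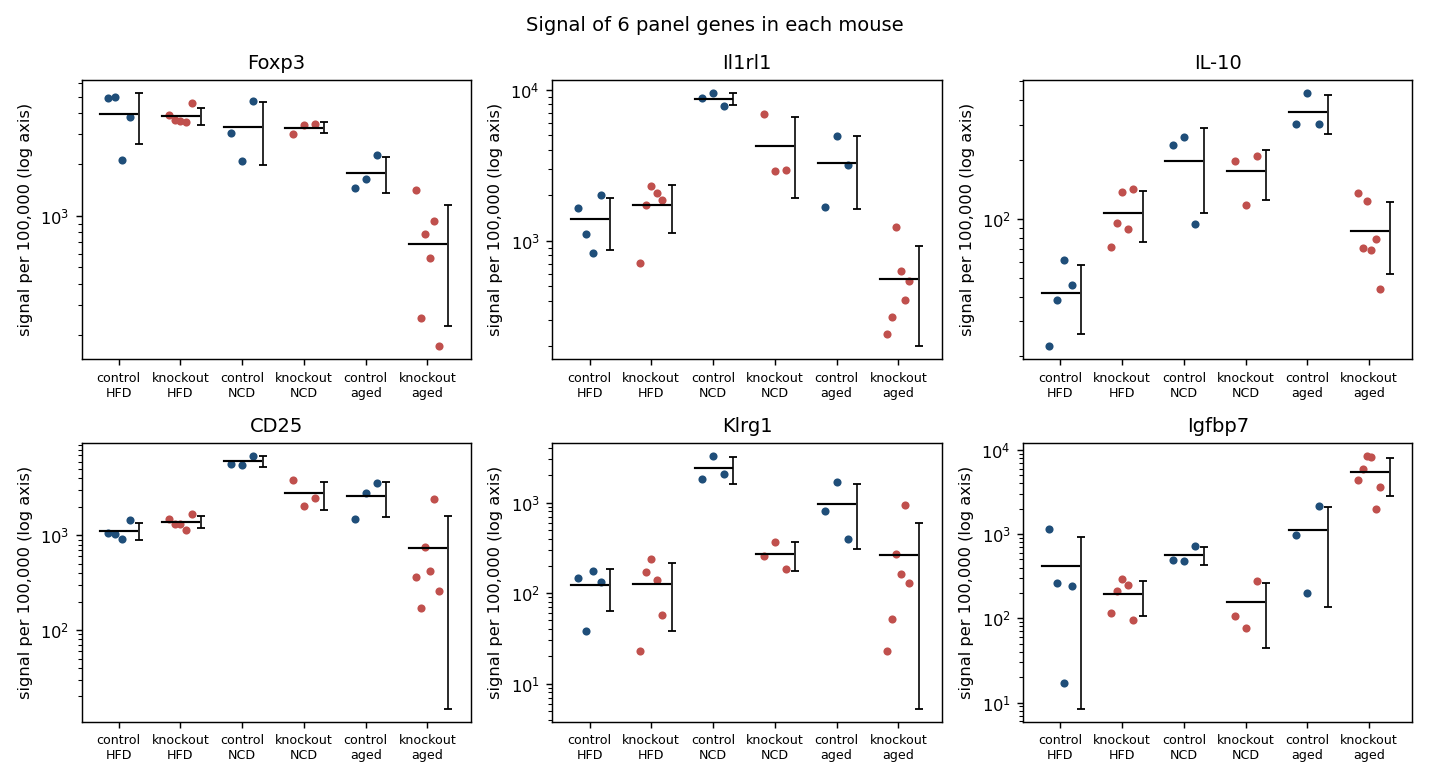
Signal per 100000 panel counts (log axis) of Foxp3, Il1rl1, IL-10, CD25, Klrg1 and Igfbp7 in each mouse, with control mice in blue and knockout mice in red. Points are mice, horizontal lines are means and vertical bars are SD, shortened where they would reach 0; in aged mice the 5 genes other than Igfbp7 have lower means in knockouts (Foxp3 687 against 1784).

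Averaged over the 3 settings with equal weights, 5 genes passed in knockout against control, 4 lower and 1 higher. These were InsR (log2 fold change -4.31, SE 0.32, adjusted p = 3.62e-10), Il1rl1 (-1.16, SE 0.30, adjusted p = 0.028), Klrg1 (-1.97, SE 0.51, adjusted p = 0.028), Ccr2 (-1.10, SE 0.31, adjusted p = 0.046) and Lmna (0.86, SE 0.25, adjusted p = 0.046). The settings differed in sign for Lmna (0.51 on HFD, 2.28 on NCD and -0.21 in aged mice) and Il1rl1 (0.29, -1.17 and -2.62). Over the 24 omissions of 1 mouse InsR passed in 24, Il1rl1 in 20, Klrg1 in 19, Ccr2 in 8 and Lmna in 5. CD25 (-1.06), Il10ra (-0.81), Cabyr (-1.30), Areg (-0.84) and S100a6 (-1.27) had the next smallest p, with adjusted p from 0.057 to 0.076. Foxp3 (-0.53), Gata3 (-0.35), IL-10 (-0.27) and Pparg (-0.20) did not pass. The visceral adipose Treg genes moved down by fry (adjusted p = 0.012), with 3 of 14 lower and 4 passing adjusted over the list alone (adjusted p = 0.84 with an estimated correlation). The Th2 list (fry adjusted p = 0.021) and the checkpoint list (0.048) also moved down, and each had adjusted p = 0.84 with an estimated correlation. The cytokine receptors (fry adjusted p = 0.00070) had adjusted p = 0.47 with an estimated correlation. The insulin list moved down by fry (adjusted p = 1.41e-06, and adjusted p = 0.84 with an estimated correlation) with a median of 0.14 and a mean of -1.20. Centring on the sample median called 8 genes, 6 of them higher, and centring on reference genes called 1. The count moved by over 1.5 times in 14 of the 24 omissions. It was 1 without NCD control replicate 2 or NCD knockout replicate 2, 2 without NCD knockout replicate 1 or aged control replicate 1, 2 or 3, and 12 without aged knockout replicate 5. It was 3 without HFD knockout replicate 1, 2, 3 or 4 or aged knockout replicate 1, 3 or 4.

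Neither interaction called a gene by limma. For genotype by diet, 12 genes had an unadjusted p under 0.05, voom called 2 and array weights 7. Among the 5 smallest p were those of Rorgt (log2 difference -4.96, SE 1.26, adjusted p = 0.063), Ccr7 (-3.16, adjusted p = 0.085), Ccr3 (-3.05) and Lmna (-1.76), the last 2 at adjusted p = 0.22. For genotype by age, 26 genes had an unadjusted p under 0.05, voom called 4 and array weights 23. The smallest p belonged to Lmna (-2.49, SE 0.64, adjusted p = 0.075), Igfbp7 (4.74), Helios (-2.03), Myadm (2.17) and Irs2 (-1.93), the last 4 at adjusted p from 0.082 to 0.084. Without aged knockout replicate 5 genotype by age called 7 genes, and without each of HFD control replicate 4, HFD knockout replicate 4, NCD control replicate 3 and NCD knockout replicate 1 genotype by diet called 1.

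In control mice, HFD against NCD called 20 genes, 17 lower and 3 higher, with a median of all genes of -0.52 log2. Il1rl1 fell from 8741 ± 836 (SD, n = 3) on NCD to 1395 ± 529 (n = 4) on HFD, a log2 fold change of -2.73 (SE 0.54, adjusted p = 0.00082). Klrg1 fell from 2397 ± 805 to 124 ± 59.7 (-4.42, SE 0.92, adjusted p = 0.0012). Pparg, the transcription factor of VAT Tregs, fell from 202 ± 59.1 to 46.9 ± 29.9 (-2.26, SE 0.49, adjusted p = 0.0015). Ccr7 rose from 244 ± 249 to 2682 ± 1080 (3.89, SE 0.64, adjusted p = 9.60e-05), as did the immediate early gene Fos (1.59, SE 0.47, adjusted p = 0.012). For 19 of the 20 genes every HFD mouse lay beyond every NCD mouse, which chance gives in 5.71% of genes not picked by p; for Myadm 3 of the 4 HFD mice did.

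Among the visceral adipose Treg genes, 4 of 14 fell in control mice on HFD (Il1rl1, Klrg1, Pparg and IL-10), and 7 passed adjusted over the list alone. The list passed by fry (adjusted p = 0.00030) and by camera with a preset correlation (0.024), but had adjusted p = 0.29 with an estimated correlation. Of the 6 list calls by camera with a preset correlation over all contrasts, 1 passed with an estimated correlation. The 3 cytokine receptors fell (fry adjusted p = 0.00013, camera adjusted p = 0.046 with a preset correlation, adjusted p = 0.29 with an estimated correlation). The suppressive effectors (2 of 6 fell, IL-10 and GzmA, fry adjusted p = 0.012) had adjusted p = 0.57 with an estimated correlation. The Th2 list (1 of 4 fell, fry adjusted p = 0.0063) had adjusted p = 0.46 with an estimated correlation. The chemokine receptor list had a median of -0.56 and a mean of 0.04, and did not pass.

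The other genes that fell in control mice on HFD were Cxcl2 (-3.28), Pcsk1 (-4.21), S100a4 (-2.51), IL-10 (-2.16), Cabyr (-3.43), Anxa1 (-2.77), CD25 (-2.46), Cxcl3 (-2.92), Furin (-1.66), Nr1d1 (-2.48), Nr4a1 (-1.26), Il10ra (-1.61), GzmA (-2.81) and Myadm (-1.53). GzmA, the measured member of the list of B, CD8 T and NK cell genes, fell with them, and the macrophage gene Lyz2 differed by -0.33 (SE 1.19). Centring on the sample median shifted the median of all genes by 0.62 log2 and called 18 genes, 12 lower and 6 higher; centring on reference genes shifted it by -0.34 and called 25, 23 lower and 2 higher. Single omissions ended the calls of 7 of the genes named here: Nr1d1 (adjusted p = 0.061), Fos (0.053) and Myadm (0.063) without NCD control replicate 2; Cxcl3 (0.065), Nr4a1 (0.077), Il10ra (0.070), Fos (0.065) and Myadm (0.072) without replicate 1; GzmA (0.090) without replicate 3; and, without HFD control replicates 2 and 4, Il10ra (0.057) and Myadm (0.078).

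In knockout mice, HFD against NCD called 17 genes, all lower. Pcsk1 fell from 1223 ± 406 (SD, n = 3) on NCD to 174 ± 62.9 (n = 5) on HFD, a log2 fold change of -2.84 (SE 0.61, adjusted p = 0.0029). Cxcl2 fell from 837 ± 257 to 224 ± 86.0 (-1.93, SE 0.43, adjusted p = 0.0034) and Rorgt from 1424 ± 1296 to 92.7 ± 79.5 (-3.64, SE 0.87, adjusted p = 0.0046). Ccr3 (-3.61), Zbtb10 (-2.54), Il5 (-3.07), Ccr1 (-3.19), Anxa1 (-2.41), Cabyr (-2.69), Nr1d1 (-2.29), S100a6 (-2.58), S100a4 (-1.19), GzmA (-2.44), Gusb (-1.31), Pparg (-1.36) and Perforin (-1.71) fell as well. For all 17 genes the 5 HFD mice lay below the NCD mean, and for 13 they lay below every NCD mouse, which chance gives in 3.57% of genes not picked by p. Among the visceral adipose Treg genes 3 of 14 fell (Pparg, Ccr1 and Ccr3), and 3 passed over the list alone. No list passed by fry; core Treg identity, with 0 of 7 members passing by limma, moved up relative to other genes by camera with a preset correlation (adjusted p = 0.032, and adjusted p = 0.60 with an estimated correlation).

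These groups differed in depth, with 11446 to 23790 counts in NCD knockouts and 34986 to 224793 in HFD knockouts. With log2 total count as a covariate 1 of the 17 calls held, and Gusb, a reference gene, was among those that fell. Centring on reference genes shifted the median of all genes by 0.36 log2 and called 8, and centring on the sample median shifted it by 0.43 and called 17, 12 lower and 5 higher. The count was 11 without HFD knockout replicate 5 and 7 without NCD knockout replicate 3. Without the latter, for example, Rorgt had adjusted p = 0.079 and Cabyr 0.15 by limma. Ccr3, Pcsk1, Zbtb10, Cxcl2, Il5 and Ccr1 passed without any single mouse. Il5 and Ccr3 had few counts, with means of 4.67 and 11 in NCD knockouts and 2 and 3.6 in HFD knockouts. Their log2 fold changes therefore rest in large part on the unlike totals. The diet calls of control and knockout mice shared 8 genes, all lower in both: Anxa1, Cabyr, Cxcl2, GzmA, Nr1d1, Pcsk1, Pparg and S100a4. Chance gives 3.54 shared genes (Fisher's exact test, one-sided p = 0.0069, with genes treated as independent). The comparisons share no samples, but they share a single estimate of each gene's spread. Mean log2 depth was also higher on HFD in both genotypes, by 0.67 in controls and 2.31 in knockouts. The p value allows for neither.

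**Figure D3:**
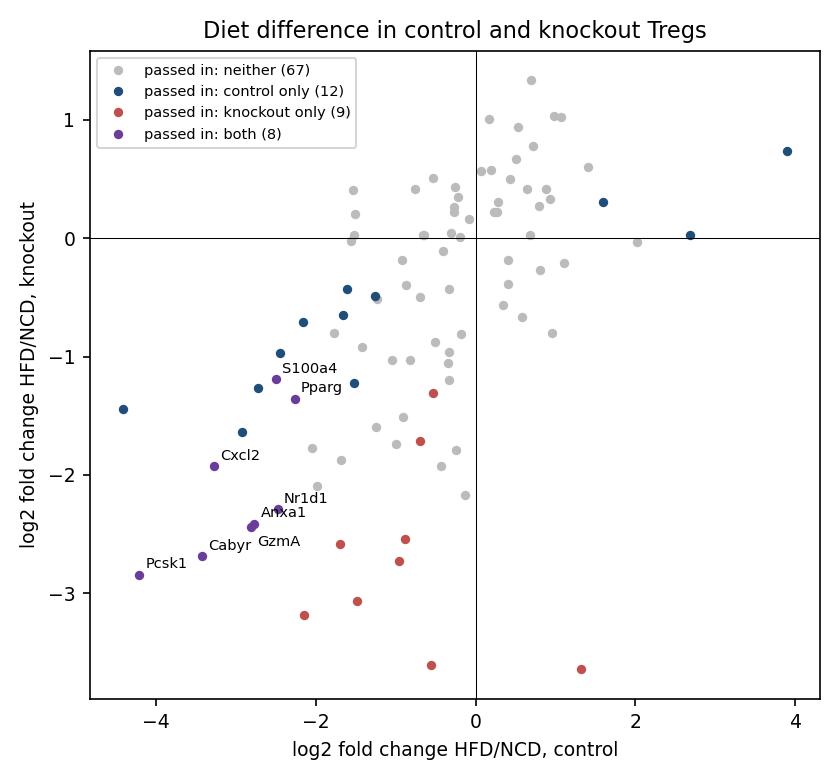
Log2 fold change of HFD against NCD for each of the 96 genes in control mice (x axis) and knockout mice (y axis). Points are genes, coloured by whether they passed in control mice, knockout mice, both or neither; the 8 genes that passed in both are named and lie below 0 on both axes.

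In control mice, aged against young called 5 genes, 3 higher and 2 lower. Lmna rose from 110 ± 21.9 (SD, n = 3) at 16 weeks to 2698 ± 369 (n = 3) at 52 weeks, a log2 fold change of 4.62 (SE 0.48, adjusted p = 2.32e-07). Mmp9 (3.93, SE 0.96, adjusted p = 0.012) and Irs2 (1.92, SE 0.46, adjusted p = 0.012) rose, and Lrig1 (-3.45, SE 0.53, adjusted p = 7.24e-05) and ICOS, a costimulatory receptor (-1.60, SE 0.46, adjusted p = 0.037), fell. Each of the 5 had all 3 aged mice beyond all 3 young mice, which chance gives in 10% of genes not picked by p. Mmp9 had 4, 3 and 8 counts in the young controls, as few as weak probes give, so the size of its rise is uncertain. InsR itself had a signal of 388 ± 112 in aged and 106.9 ± 49.7 in young controls and did not pass (log2 fold change 1.92, SE 0.62, adjusted p = 0.074), nor did Irf4 (1.70), Ccr4 (-2.00), Helios (-1.35) and Atf3 (1.31), at adjusted p from 0.074 to 0.095. The insulin list moved up by fry (adjusted p = 0.0059), with 1 of 3 higher and 3 passing adjusted over the list alone (adjusted p = 0.45 with an estimated correlation). Core Treg identity moved down (fry adjusted p = 0.015, 1 of 7 lower, 3 over the list alone) and so did the Th2 list (fry adjusted p = 0.015, 0 of 4 passing by limma, 2 over the list alone); both had adjusted p = 0.45 with an estimated correlation. Lyz2 differed by 2.88 (SE 1.28) and did not pass.

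Centring on the sample median called 6 genes in aged against young controls, 5 higher, with a shift of 0.12 log2, and centring on reference genes called 5, 4 higher, with a shift of 0.37. Lmna and Lrig1 passed without any single mouse. ICOS failed without any of the 6 mice (adjusted p up to 0.15, without aged control replicate 1). Irs2 failed without NCD control replicate 2 (0.058) or 3 (0.082) or aged control replicate 3 (0.058), and Mmp9 without NCD control replicate 3 (0.065) or aged control replicate 1 (0.081). The count was 2 without NCD control replicate 3 and 3 without NCD control replicate 2 or aged control replicate 1.

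In knockout mice, aged against young called 52 genes, 40 lower and 12 higher, with a median of all genes of -0.82 log2. Foxp3 fell from 3284 ± 245 (SD, n = 3) to 687 ± 463 (n = 6), a log2 fold change of -2.59 (SE 0.50, adjusted p = 0.00024). Helios fell from 2806 ± 738 to 307 ± 228 (-3.38, SE 0.39, adjusted p = 1.47e-06), and ICOS from 1655 ± 867 to 206 ± 65.4 (-2.93, SE 0.40, adjusted p = 8.74e-06). Igfbp7 rose from 154 ± 110 to 5452 ± 2606 (5.19, SE 0.88, adjusted p = 6.43e-05), Anxa1 by 3.08, Myadm by 2.93, Lmna by 2.13, Fosb by 2.11 and Atf3 by 2.04. The macrophage gene Lyz2 rose as well, from 147 ± 69.6 to 1977 ± 2483 (2.96, SE 1.11, adjusted p = 0.028). For all 25 genes named by rank the 6 aged mice lay beyond the young mean, and for 21 they lay beyond every young mouse, which chance gives in 2.38% of genes not picked by p.

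Core Treg identity had 6 of 7 members that fell with age in knockouts (all but Nrp1), and 6 passed adjusted over the list alone. It passed by fry (adjusted p = 1.27e-06) and by camera with a preset correlation (0.039), but had adjusted p = 0.35 with an estimated correlation. All 6 suppressive effectors fell (fry adjusted p = 1.27e-06, adjusted p = 0.35 with an estimated correlation). All 4 Th2 genes fell (fry adjusted p = 1.56e-05, adjusted p = 0.36 with an estimated correlation), though Il5 had only 1 to 6 counts in each of these mice. The checkpoint receptors had 4 of 6 that fell and the cytokine receptors 2 of 3 (fry adjusted p = 2.59e-05 for each, adjusted p = 0.41 with an estimated correlation). The visceral adipose Treg genes had 7 of 14 that fell and 1, Ccr2, that rose (fry adjusted p = 0.0066), and 8 passed over the list alone. The chemokine receptor list had 5 of 9 that fell and 1 that rose (fry adjusted p = 0.011); both had adjusted p = 0.92 with an estimated correlation. The insulin list (1 of 3 fell, IGF1R, fry adjusted p = 0.011) had adjusted p = 0.93 with an estimated correlation, and the reference genes (1 of 4 fell, Hprt, fry adjusted p = 0.030) had adjusted p = 0.92 with an estimated correlation.

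Further genes named by rank, all lower in aged knockouts, were Lrig1 (-2.92), Il1rl1 (-3.01), Zbtb10 (-3.20), Pcsk1 (-3.54), Pdcd1 (-2.64), Satb1 (-3.74), S100a6 (-3.62), Ebi3 (-1.77), CD25 (-2.48), Ccr4 (-2.43), Areg (-1.79), Rorgt (-3.25), AdipoR2 (-1.11), GzmA (-2.74) and Nfkbid (-2.45). RoRa, the measured member of the Th17 and Tfh list, also fell (-2.01, SE 0.69, adjusted p = 0.021). Centring on the sample median shifted the median of all genes by 0.76 log2 and called 32 genes, 16 higher, and centring on reference genes shifted it by 0.58 and called 33, 15 higher. The insulin and reference gene lists changed sign after centring on the sample median. ICOS, Lmna and Lrig1 passed in both genotypes; chance gives 2.71 shared genes between the 5 and 52 calls (Fisher's exact test, one-sided p = 0.58).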

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

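The tests on other splits of the samples were fixed before their results were seen; the counts of splits that leave out InsR, the test of the aged against HFD difference, and the tests of depth, scaling, Treg share and column sums, were chosen after the patterns were seen.

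Other splits of the same samples were used to ask whether chance can be excluded for each count. In aged mice knockout against control called 23 genes, which 1 of 84 splits, the real one, reached (highest other 17). HFD against NCD called 20 genes in controls (1 of 35 splits, highest other 16) and 17 in knockouts (1 of 56, highest other 3). Aged against young knockouts called 52 genes (1 of 84, highest other 20). Chance is less likely for these counts but not excluded, since the splits are few and were not adjusted over the contrasts. The mean effect reached its 5 genes in 2 of 100 splits. Another split called as many (highest other 5), so chance is less likely there rather than excluded. InsR, the deleted gene, adds 1 call to each real count of knockout against control. Counting genes other than InsR, chance is likewise less likely but not excluded in aged mice (22 genes, 1 of 84 splits, highest other 16). For the mean effect another split again called as many (4 genes, 2 of 100, highest other 4), so chance is less likely rather than excluded. On HFD it is not excluded for the 1 gene other than InsR, Rorgt (8 of 100 splits, highest other 3); with InsR the count of 2 was reached in 3 of 100 splits (highest other 3). Splits are too few for knockout against control on NCD (5 genes, highest other 0 of 10 splits, value 1; 4 genes other than InsR, highest other 0) and for aged against young controls (5 genes, highest other 1, 10 splits). The interactions called 0 genes, so all 100 of 100 splits reached that count, with highest others of 2 for diet and 6 for age, and chance is not excluded.

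The genotype effect differed between aged and HFD mice for 12 genes in a contrast chosen after the data were seen (limma, Benjamini-Hochberg over 96 genes). IL-10, the suppressive cytokine, had a log2 difference of -3.43 (SE 0.58, adjusted p = 0.00050), with knockout against control at 1.36 on HFD and -2.07 in aged mice. IL-10 passed under all 14 settings and 18 omissions tried for it. Il1rl1 (-2.91), Helios (-2.19), Il10ra (-2.36), Pcsk1 (-3.12), CD25 (-2.68), Tbet (-2.95), Dgat1 (-2.78), Pdcd1 (-2.09), ICOS (-1.73) and Tnfrsf9 (-2.44) were lower and Myadm (1.87) higher. Centring on the sample median shifted the median of all genes by 0.84 log2 and called 8 genes, 7 of them higher, and of the 12 it kept 2. Centring on 4 reference genes shifted it by -0.48 and called 16 genes, all lower, with 11 of the 12 among them. The count was 5 without aged control replicate 2 or 3 and 21 without aged knockout replicate 1 or 5. In 3 of 100 splits of the mice within each setting at least 12 genes passed (highest other 18), but the contrast was picked for its difference, so these splits do not settle whether chance is excluded.

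The 17 genes lower on HFD than NCD in knockout mice came from groups that differ by 2.31 in log2 depth. In control mice the HFD minus NCD mean of the 17 genes was -1.85 (SE 0.22), below the -0.67 that depth alone would give by more than 2 SE. That shows a difference beyond depth in controls and does not settle the cause in knockouts. There the recovered counts of the 17 genes changed by a median of -0.27 log2, and 11 of them averaged under 50 counts in NCD knockouts. Near-constant counts over unlike totals give such a fall, so depth as the whole cause is not excluded in knockouts. A part due to depth cannot be told apart, because the totals of the 2 groups do not overlap: with log2 total count as a covariate 1 of the 17 passed, the median log2 fold change going from -2.54 (SE 0.61) to -1.61 (SE 0.69). The calls ended through a smaller difference and a wider error. Diet itself stays open as an untested biological explanation.

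The 20 genes lower in aged knockouts include Foxp3, the sorting marker. Scaling to a fixed total as the whole cause cannot be told apart: after centring on the sample median 2 of the 20 still passed, InsR, which is the deleted gene, and Il1rl1, where the bound asked for at least 10. That bound was reworded after the result was known. An earlier one, which the median of the 20 (-1.16, SE 0.53) met narrowly, also allowed a median below 0 by over 2 SE, and another asked for 1 gene. For the other 18 the median went from -2.00 (SE 0.56) to -1.12 (SE 0.54) and the calls ended, while centring on 4 reference genes left 17 of the 18 called (median -2.17, SE 0.58). Scaling cannot be told apart for these 18 either: the centrings disagree, no value shows which genes genotype leaves unchanged, and genes picked as lowest stay low under any common shift. The 5 strongest genes of each sample held 49.5% to 58.2% of the signal in aged knockouts other than replicate 5 (36.9%). In aged controls the share was 31.6% to 37.4%. Under a fixed total this leaves less signal for the other genes, so scaling may carry part of the fall. A lower share of Tregs among the sorted cells may contribute and stays open. Igfbp7 rose by 2.50 more than 4 macrophage genes (SE 1.52, exact permutation p = 0.095 over 84 splits). That difference cannot test the share, since a single other cell type could raise Igfbp7 and leave macrophage genes unchanged. The T cell receptor gene Tcra differed by -2.68 (SE 1.05, adjusted p = 0.064 by limma) and did not pass. Relative to Foxp3, InsR was still called lower by limma (-4.01, adjusted p = 0.0011). Of the lower genes other than InsR and Foxp3, 18 in number, limma called 0 (0 with unadjusted p under 0.05, median -0.34). Foxp3 was itself picked as lower, so setting the other picked genes against it brings them toward no difference by construction. The 4 reference genes, Gusb (1.83), Hprt (1.79), Rpl19 (1.78) and Sdha (2.05), were all called higher relative to Foxp3. The sort on Foxp3(YFP) should remove cells other than Tregs. Igfbp7, Lyz2, Lgals3, Mmp12 and Ptafr were chosen as markers after the data were seen. A change within Tregs by genotype remains untested.

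All 10 control samples and 2 of 14 knockout samples sum to more than 100000 (Fisher's exact p = 6.73e-05), by up to 1.27-fold. Genes left out of the authors' total are argued against as a single explanation, since the best set of up to 3 genes equals the excess in 2 of the 12 samples. After rescaling, 125 of 129 calls remained, which argues against a scale common to all genes of a sample as their source. Rescaling changes all genes of a sample alike, so an excess held in few genes was not tested. The comparisons within knockouts, with 52 and 17 of the calls, could hardly change, since knockout sums ran from 100000 to 100422. The origin of the larger sums was not found.

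Each named gene and the total count were tested for a single outlying value within the HFD control, HFD knockout and aged knockout groups. Of the 94 tests, 13 found such a value. Chance gives about 4.7 for independent tests on normal values, whereas these tests share mice and used values that were not logged. Aged knockout replicate 5 was highest for CD25 (2420), Helios (763), InsR (18.6), Klrg1 (931) and Pdcd1 (805). Its InsR value was 4 counts, as in aged knockout replicate 4, and stood out because its total (21487 counts) was the lowest of the group. Without it the aged comparison called 32 genes, 23 of them shared with the 23 called. Aged knockout replicate 6 was highest for GzmA (254), and aged knockout replicate 1 for total count (135141). HFD control replicate 3 was highest for Areg (1346) and lowest for Furin (253), and HFD control replicate 2 was highest for Ccr7 (4294) and Nr1d1 (40.01). HFD knockout replicate 2 was highest for Pparg (123) and HFD knockout replicate 3 for S100a6 (322).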

How the results depend on the processing

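Counts of genes passing under each alternative follow in the order of the comparisons; rescaling, voom, the depth covariate, the 20-count filter, omissions for list tests and everything on the aged against HFD difference were chosen after the data were seen. Of the 165 gene values and 31 list calls followed over the alternatives, 3486 gene checks kept direction and side of the threshold, 364 lost the call, 120 gained it and 24 changed sign, none of the 24 in a gene that passed. Unless the alternative's own construction shows it, the cause was not tested. Fewer genes or samples enter the fits of the filters, of only the groups compared, and of the omissions.

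For knockout against control on HFD (2 genes), the count was 1 without the 24 genes with the lowest mean, 1 with only the groups compared, 1 with a replicate block, 1 without genes under 20 counts, 5 with array weights and 4 with voom. On NCD (5 genes) it was 3 after centring on reference genes, 3 with a replicate block and 8 with array weights. In aged mice (23 genes) it was 5 with only the groups compared and 46 with array weights. For HFD against NCD in knockouts (17 genes) it was 8 after centring on reference genes, 28 with array weights and 1 with the depth covariate. For aged against young it was 19 with array weights and 10 with voom in controls (5 genes), and 32 after centring on the sample median and 33 on reference genes in knockouts (52 genes). For HFD against NCD in controls (20 genes) no alternative moved the count by over 1.5 times. The numbering does not pair the samples, since same-numbered samples did not correlate above 0.1 in every pair of any contrast, so the replicate block has no design behind it.

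Genotype by diet (0 genes) called 1 with a pseudocount of 10, without the 24 lowest genes, after centring on the sample median, with a variance trend, with the depth covariate and without genes under 20 counts, 2 after rescaling, 2 with voom and 7 with array weights. Genotype by age (0 genes) called 8 with a pseudocount of 10, 3 without the 24 lowest genes, 1 after centring on the sample median, 3 with only the groups compared, 23 with array weights, 3 with a variance trend, 1 after rescaling, 4 with voom and 1 without genes under 20 counts. The mean genotype effect (5 genes) called 8 with a pseudocount of 10, 8 without the 24 lowest genes, 8 after centring on the sample median, 1 on reference genes, 21 with array weights, 10 with a replicate block and 15 with the depth covariate. The aged against HFD difference (12 genes) called 35 with array weights and 23 with voom. Fry called 31 lists. Camera with a preset correlation called 6, 5 of them among the 31, and with an estimated correlation 1, also among them; fry after centring on the sample median called 19, 17 of them among the 31.

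Leaving out each sample in turn gave 1 to 3 genes for knockout against control on HFD, 2 to 5 on NCD, 9 to 32 in aged mice and 1 to 12 for their mean. It gave 16 to 26 for HFD against NCD in controls and 7 to 16 in knockouts, and 2 to 5 for aged against young in controls and 37 to 56 in knockouts. It gave 0 to 1 for genotype by diet, 0 to 7 for genotype by age, 5 to 21 for the aged against HFD difference and 28 to 35 list calls. For knockout against control on HFD, 1 came without HFD control replicate 1 or 2 or HFD knockout replicate 5, and 3 without HFD control replicate 3. On NCD, 5 came without NCD knockout replicate 3, and in aged mice 32 came without aged knockout replicate 5. For HFD against NCD in controls, 16 came without NCD control replicate 1 or 2 and 26 without NCD control replicate 3; in knockouts 16 came without HFD knockout replicate 3. For aged against young, 5 came in controls without aged control replicate 3, and in knockouts 37 came without NCD knockout replicate 1 and 56 without aged knockout replicate 1. Of the list calls, 28 came without NCD knockout replicate 3 and 35 without aged knockout replicate 5. For the aged against HFD difference, 5 came without aged control replicate 2 or 3 and 21 without aged knockout replicate 1 or 5. The mice behind the other ends are named with their comparisons.

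Values that changed sign (log2 fold change, knockout against control) belonged to genes that did not pass. On HFD, Foxp3 (0.03) was -0.18 with array weights, -0.057 with a replicate block and -0.24 to 0.17 over the omissions (below 0 without control replicate 3 or knockout replicate 5). Klrg1 (-0.18) was 0.13 after centring on reference genes, 0.15 with array weights and -0.67 to 0.32 over the omissions (above 0 without control replicate 3 or knockout replicate 1). Areg (-0.09) was 0.22 after centring on reference genes, 0.014 with array weights and -0.15 to 0.058 over the omissions (above 0 without knockout replicate 3 or control replicate 3). On NCD, Foxp3 (0.07) was -0.32 after centring on reference genes and -0.21 to 0.37 over the omissions (below 0 without control replicate 2). IL-10 (-0.09) was 0.14 after centring on the sample median, 0.084 after rescaling, 0.18 with voom and -0.56 to 0.18 over the omissions (above 0 without control replicate 1 or 2 or knockout replicate 2). After centring on the sample median, Pparg (-0.54) was 0.34 in aged mice, and for the mean effect Pparg (-0.20) was 0.17, Gata3 (-0.35) 0.024 and IL-10 (-0.27) 0.11. The insulin list (mean 0.22) and the reference genes (mean 0.18) turned upward in aged against young knockouts under the same centring.

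Depth limits what the 3 NCD knockout samples (11446 to 23790 counts) can show for weakly expressed genes.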
